A study of Mus musculus with 6 samples.

How the data were processed

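Total RNA was extracted with Trizol, per the labels' protocols, from renal tubular epithelial cells that had been released from mouse kidneys by collagenase digestion. The kidneys had gone through 30 min of ischemia and 24 h of reperfusion. Biotin-labelled targets were hybridised to Affymetrix whole-transcript arrays, 1 array per sample, with 3 arrays from vehicle-treated and 3 from PT2385-treated mice. The labels name the samples IR and IRPT and the protocol describes vehicle and PT2385 arms. IRPT was therefore taken as the PT2385 arm and IR as the vehicle arm. The protocol writes the compound as PT2385 for the arm and as PT2384 for the injections, and PT2385 is used throughout here.

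The deposited values are summarised log2 signals, 1 per transcript cluster (the array's unit of measurement, roughly a gene) and array, and they ran from about 2 to 13.5. Transcriptome Analysis Console is named in the submitters' processing notes without a version. The summarisation, background correction and normalization methods are not given in the sources used here, so no step was undone or repeated in the primary comparison. The median of the clusters tested lay between 6.20 and 6.25 in every array and the quartiles were also close, so the arrays were already near a common scale. The small offset that remained followed the groups, with medians of 6.196 to 6.199 in the vehicle arrays and 6.235 to 6.248 in the PT2385 arrays.

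The value table held 28846 rows. The 6640 control rows were left out, and the other 22206 transcript clusters were all tested, with no filter on dim signals. The annotation used gave 1 gene symbol to 19572 clusters, several to 0 and none to 2634. Updating symbols through Entrez gene IDs against the RefSeq mouse gene table (GRCm38.p6) changed 0 symbols. That table served for names only, and chromosomes were read from the cluster identifiers. A gene with several clusters, which 55 genes had, was represented by the cluster with the highest mean over the 6 arrays.

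The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes on the log2 values with treatment as the only term. Tests were 2-sided and p-values were adjusted by the Benjamini-Hochberg method over all clusters, with a threshold of 0.05. Differences are PT2385 minus vehicle on the log2 scale, with the SE from the moderated variance. A screen common for this kind of array, an unadjusted p under 0.05 with at least a 2-fold difference, was counted beside it. Gene lists for nephron segments, other kidney cells, hypoxia, injury, stress, metabolism and inflammation were tested as sets with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 29 lists with at least 5 measured members. Of the 783 different genes in the 30 lists, 702 were measured, after 8 older symbols had been replaced by current ones. Each set was also tested with its correlation estimated from the data and with fry, a rotation test.

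The tests, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 higher and 10 lower genes with the largest difference among those past the threshold whose groups did not overlap, leaving out predicted genes, clone and pseudogene names and chemosensory receptors. It added 10 genes named in advance for the study's subject. From each list it added up to 4 members past the threshold with the largest difference, or, where none passed, the 2 with the smallest unadjusted p as values only. Alternatives were the replicate number as a block, other normalizations of the values, filters on dim clusters, 1 cluster per gene, other variance priors, array weights and the omission of each array in turn. Omission of the X and Y chromosomes was added after seeing the data.

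The fit was tested on simulated arrays with the observed means and spreads over 22206 clusters, 3 against 3. It recovered 10% of 50 clusters changed by 0.5 on the log2 scale, 86% of those changed by 1 and 100% of those changed by 2 or 3, with 10 false calls, and it made 0 calls when nothing was changed. Small differences are therefore often missed at this size. The simulated noise was drawn independently for each cluster, so the counts of false calls do not cover noise shared between genes. No detection calls were used. The 23 background control rows lay between 2.41 and 7.47 depending on the probe, so no single signal level separates expressed from unexpressed genes. The number of arrays limits the precision. Nothing in the labels says whether the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. The highest share of clusters with equal values in any pair of arrays was 0.234%, so no array was a copy of another.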

Results

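Gene expression was measured in tubular epithelial cells isolated from mouse kidneys after 30 min of ischemia and 24 h of reperfusion, a model of acute kidney injury. The mice had received vehicle (3 arrays) or PT2385 (3 arrays), an inhibitor that keeps hypoxia-inducible factor HIF-2α from pairing with its partner ARNT. PT2385 was given at 10 mg/kg, 16 h before surgery and 1, 8 and 20 h after it, although the protocol writes the injected compound as PT2384. The series title concerns Atp4a, which encodes the catalytic subunit of the gastric-type H,K-ATPase, as a target regulated by hypoxia in acute kidney injury. Samples without ischemia were not analysed here, so each difference is between treatment arms after injury. The first principal component held 44.6% of the variance and separated the groups, with scores from -23.9 to -16.7 in the vehicle arrays and from 9.70 to 29.5 in the PT2385 arrays. The second held 23.3% and spread the PT2385 arrays widely, with 21.1, -9.82 and -24.4 for replicates 1, 2 and 3, against -4.52 to 9.36 in the vehicle arrays. Correlations across genes were 0.993 to 0.994 within the vehicle group, 0.988 to 0.995 within the PT2385 group and 0.983 to 0.990 between groups.

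The question of the comparison was which transcripts differ between injured tubular cells of the vehicle and PT2385 arms. The genes with the smallest p-values included genes of the Y chromosome. Eif2s3y, a translation initiation factor gene, had a mean log2 signal of 9.20 ± 0.10 (SD, n = 3) in the vehicle group and 3.21 ± 0.16 (SD, n = 3) in the PT2385 group. Uty, a histone demethylase gene, had 8.66 ± 0.09 and 2.99 ± 0.23, and Kdm5d, also a histone demethylase gene, had 6.47 ± 0.12 and 3.32 ± 0.07 (SD, n = 3 each). The PT2385 means lay under the median of the background control rows (3.60), so no fold is given for these genes. The labels give no sex of the animals. The Y-linked values go with male vehicle and female PT2385 mice. Every difference below was therefore measured between groups that also differ in Y-linked transcripts in all 6 arrays. For none of them can an effect of PT2385 be told apart from a difference in sex.

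Of 22206 transcript clusters, 184 passed the threshold, 74 of them higher and 110 lower in the PT2385 group. Of these, 160 had a gene symbol, 84 differed at least 2-fold, 9 lay on the Y chromosome and 4 on the X chromosome. The screen by unadjusted p and 2-fold difference held 73 higher and 80 lower clusters. The values of the groups did not overlap for 20.7% of clusters, where chance gives 10%. Centring each array on its median gave 57 higher and 135 lower calls. The number of calls was 42 without PT2385 replicate 2, 81, 65 and 72 without vehicle replicates 1, 2 and 3, and 456 with array weights. Leaving out the X and Y chromosomes, an alternative chosen after seeing the data, gave 150 calls.

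Among autosomal genes, the largest falls included enzymes and transporters of the proximal tubule. Acsm3, a medium-chain acyl-CoA synthetase gene, fell from 10.17 ± 0.44 to 5.03 ± 0.22 (SD, n = 3 each), a difference of -5.14 (SE 0.21, adjusted p = 1.08e-05). The cytochrome P450 gene Cyp2j13 was lower by -4.88 (SE 0.18, adjusted p = 5.46e-06) and the organic anion transporter gene Slco1a1 by -4.65 (SE 0.22, adjusted p = 2.98e-05). The amino acid transporter gene Slc7a13 differed by -4.09, the fatty acid hydroxylase gene Cyp4a12a by -3.30, the protease inhibitor gene Pzp by -3.28 and the carboxylesterase gene Ces1f by -3.00, with adjusted p between 2.14e-06 and 0.00476. Among genes with higher values, Akr1c18, which encodes a progesterone-metabolising aldo-keto reductase, was higher in the PT2385 group, with 10.61 ± 0.79 against 5.50 ± 0.43 (SD, n = 3 each), a difference of 5.11 (SE 0.37, adjusted p = 0.000484). The amino acid transporter gene Slc7a12 differed by 4.64 (SE 0.58, adjusted p = 0.0131), Ceacam2 by 2.88, the serpin gene Serpina1f by 2.79 and the stearoyl-CoA desaturase gene Scd1 by 2.68. The other genes with the largest rises were Slc22a13 (2.41), Abca13 (2.33), Slc22a13b (2.15), the branched-chain aminotransferase gene Bcat1 (2.06) and, on the X chromosome, the bone morphogenetic protein antagonist gene Chrdl1 (2.26). In the dimmer group, all 3 of Slco1a1 (4.39), Pzp (3.96) and Chrdl1 (4.28) had means no higher than the highest array median of the negative control rows (4.47), so their differences are lower bounds in size and their rank is not exact. The dimmer means of the other genes named in this paragraph lay between 5.03 and 7.41, inside the range of the background control rows (2.41 to 7.47), so these differences can also be understated. Of these 10 higher genes, Slc7a12, Slc22a13, Abca13, Chrdl1, Slc22a13b and Bcat1 lost the call when PT2385 replicate 2 or other single arrays were left out, with the highest adjusted p over all alternatives between 0.0847 and 0.194. An eBayes fit with a trend and robust hyperparameters also ended the calls of Slc7a12 (adjusted p = 0.0543), Slc22a13 (adjusted p = 0.0971) and Abca13 (adjusted p = 0.10).

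**Figure D1:**
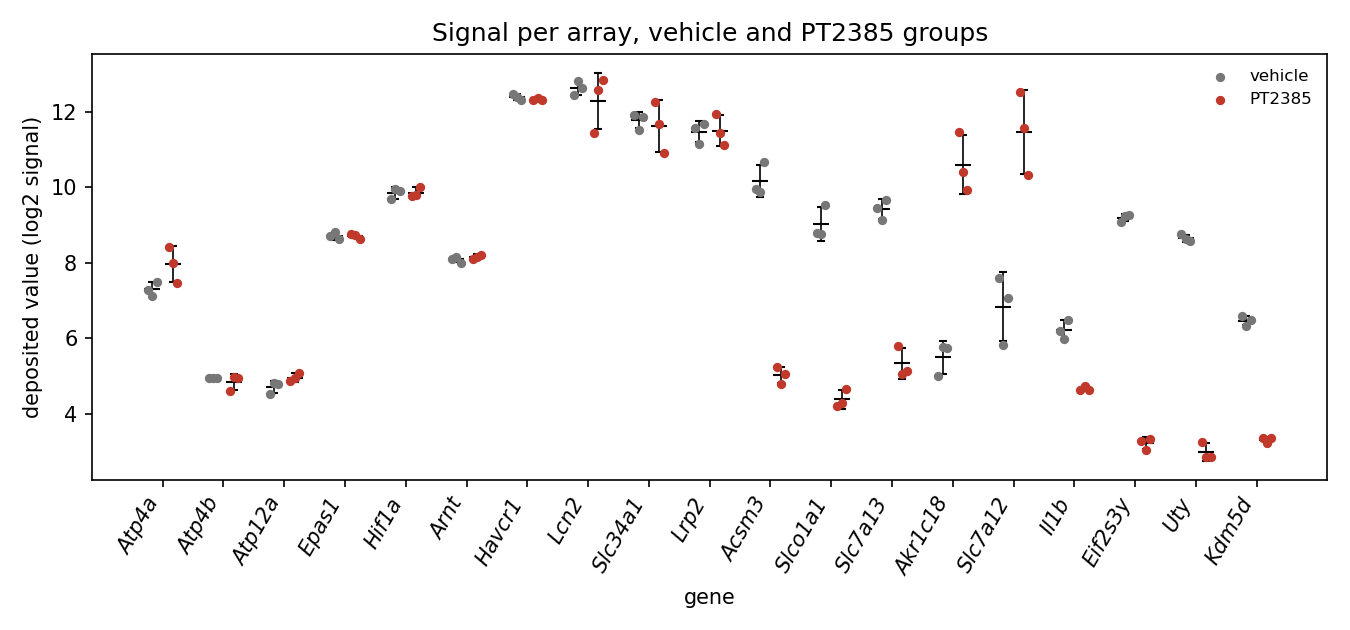
The vertical axis gives the deposited log2 signal per array for each gene on the horizontal axis, grey for the 3 vehicle and red for the 3 PT2385 arrays, with black marks for the mean and bars for the SD. The Y-linked genes Eif2s3y, Uty and Kdm5d were far lower in every PT2385 array, while the values of Atp4a overlapped between the groups, with means of 7.30 and 7.97.

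Atp4a did not pass the threshold. Its signal (cluster TC0700000573.mm.2) was 7.28, 7.12 and 7.49 in the vehicle arrays and 8.43, 7.99 and 7.48 in the PT2385 arrays, a difference of 0.67 (SE 0.22, adjusted p = 0.230). The other catalytic subunit gene of this pump family, Atp12a, had a difference of 0.25 (SE 0.12, adjusted p = 0.378), and the beta subunit gene Atp4b had -0.10 (SE 0.12, adjusted p = 0.719). Their group means lay between 4.71 and 4.96, and the vehicle mean of Atp4a was 7.30, all within the range of the background control rows (2.41 to 7.47). Of the 3 genes, 0 passed over all clusters and 1, Atp4a, when adjusted over the list alone. The Na,K-ATPase and FXYD subunit list was shifted up as a set (7 measured, median 0.12, adjusted p = 0.0370, and adjusted p = 0.308 with an estimated correlation), with 0 members past the threshold over all clusters and 0 adjusted over the list alone. Its members with the smallest p were Fxyd1 (0.32) and Fxyd6 (0.25). This shift lost its call without any 1 of 5 single arrays, with adjusted p = 0.103 without PT2385 replicate 3. The V-type H-ATPase list showed no shift (17 measured, adjusted p = 0.625), and its median (-0.02) and mean (0.02) differed in sign. Its members with the smallest p were Atp6v0a1 (-0.47) and Atp6v1c2 (0.55).

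No transcript of the hypoxia lists passed the threshold over all clusters. Epas1, which encodes HIF-2α, differed by -0.01 (SE 0.10), Hif1a by 0.01 (SE 0.12) and Arnt by 0.07 (SE 0.09), with adjusted p between 0.777 and 0.977. Of 12 measured HIF pathway components 0 passed, and the set test gave adjusted p = 0.208, with Siah2 at -0.32 and Arnt2 at -0.29. Of 24 measured HIF-2-linked targets 0 passed, over all clusters or adjusted over the list alone, with adjusted p = 0.379 for the set. Some of these targets were dim, with vehicle and PT2385 means of 4.25 and 4.60 for Epo and 4.74 and 4.28 for Arg1. These lay near the highest array median of the negative control rows (4.47), so a difference in such genes could be missed. The median of this list was 0.01 while its mean was -0.10 and its test pointed down. Its members with the smallest p were the vasodilator peptide gene Adm (-0.99, SE 0.27, adjusted p = 0.174) and the iron transporter gene Slc11a2 (-0.32, SE 0.10, adjusted p = 0.204). The list of glycolysis and HIF-1-linked targets had a median of 0.07 over 29 genes and adjusted p = 0.0653, which became 0.00837 with quantile normalization, 0.00461 with cyclic loess and 0.0315 without PT2385 replicate 1. With an estimated correlation its adjusted p = 0.308. Of its members 0 passed over all clusters and 4 adjusted over the list alone. The smallest p values belonged to the hexokinase gene Hk1 (0.66, adjusted p = 0.0566) and the pyruvate kinase gene Pkm (0.54, adjusted p = 0.0764).

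Proximal tubule genes moved in both directions. Of 51 measured members 8 were lower and 2 higher past the threshold, and 12 and 4 when adjusted over the list alone. Acsm3, Slco1a1 and Slc7a13 were among the lower ones and Slc7a12 was higher. The endocytic receptor gene Lrp2 differed by 0.03 (SE 0.21) and the phosphate transporter gene Slc34a1 by -0.15 (SE 0.30), with adjusted p of 0.963 and 0.847. The mixed test of fry, which counts changes in either direction, gave adjusted p = 0.000159 for this list and 0.305 for a shift one way. The mixed test does not compare a list with other genes, and 14.5% of all clusters had an unadjusted p under 0.05. Its pass therefore does not show that proximal tubule genes moved more than genes at large. As a set the list was shifted down (median -0.09, adjusted p = 0.00147), with adjusted p = 0.663 with an estimated correlation and adjusted p = 0.373 without PT2385 replicate 3. The fatty acid oxidation and peroxisome list was also shifted down (36 measured, median -0.19, adjusted p = 0.000181, and adjusted p = 0.541 with an estimated correlation), with 2 higher and 9 lower adjusted over the list alone. Its 1 member past the threshold over all clusters, the fatty acid hydroxylase gene Cyp4a14, was higher (1.42, SE 0.24, adjusted p = 0.0431). The call of Cyp4a14 was lost without vehicle replicate 2 or any 1 of the PT2385 arrays, with adjusted p up to 0.199, and with a robust eBayes fit (adjusted p = 0.0570). The oxidative phosphorylation list was shifted up (41 measured, median 0.17, adjusted p = 9.62e-06, and adjusted p = 0.541 with an estimated correlation) with 0 members past the threshold over all clusters or the list alone. Ndufa5 (0.38) and Cox7b (0.29) had its smallest p values. The same groups differ in Y-linked transcripts, as given above for Eif2s3y.

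Markers of the distal nephron mostly had higher values in the PT2385 group. Of 20 measured markers of the loop of Henle and distal convoluted tubule 19 had a positive difference, with a median of 0.55. The tight junction gene Cldn19 rose by 1.24 (SE 0.18, adjusted p = 0.0259) and the phosphatase inhibitor gene Ppp1r1a by 1.14 (SE 0.17, adjusted p = 0.0276). These 2 passed over all clusters and 13 higher members when adjusted over the list alone. Both lost the call without vehicle replicate 1, vehicle replicate 2 or PT2385 replicate 2, with adjusted p up to 0.149. Of 21 collecting duct markers 20 had a positive difference, with a median of 0.42. Of these, 0 passed over all clusters and 12 adjusted over the list alone. The water channel gene Aqp2 had 1.10 (SE 0.20, adjusted p = 0.0552) and the sodium channel gene Scnn1b had 0.54 (SE 0.10, adjusted p = 0.0535). The set tests gave adjusted p = 6.24e-10 for the loop and distal list and adjusted p = 9.58e-10 for the collecting duct list, and adjusted p = 0.308 for each with an estimated correlation. The mean difference of the loop and distal markers from their average over the 6 arrays was 0.776, 0.338 and 0.0465 in the 3 PT2385 arrays and between -0.437 and -0.351 in the vehicle arrays.

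**Figure D2:**
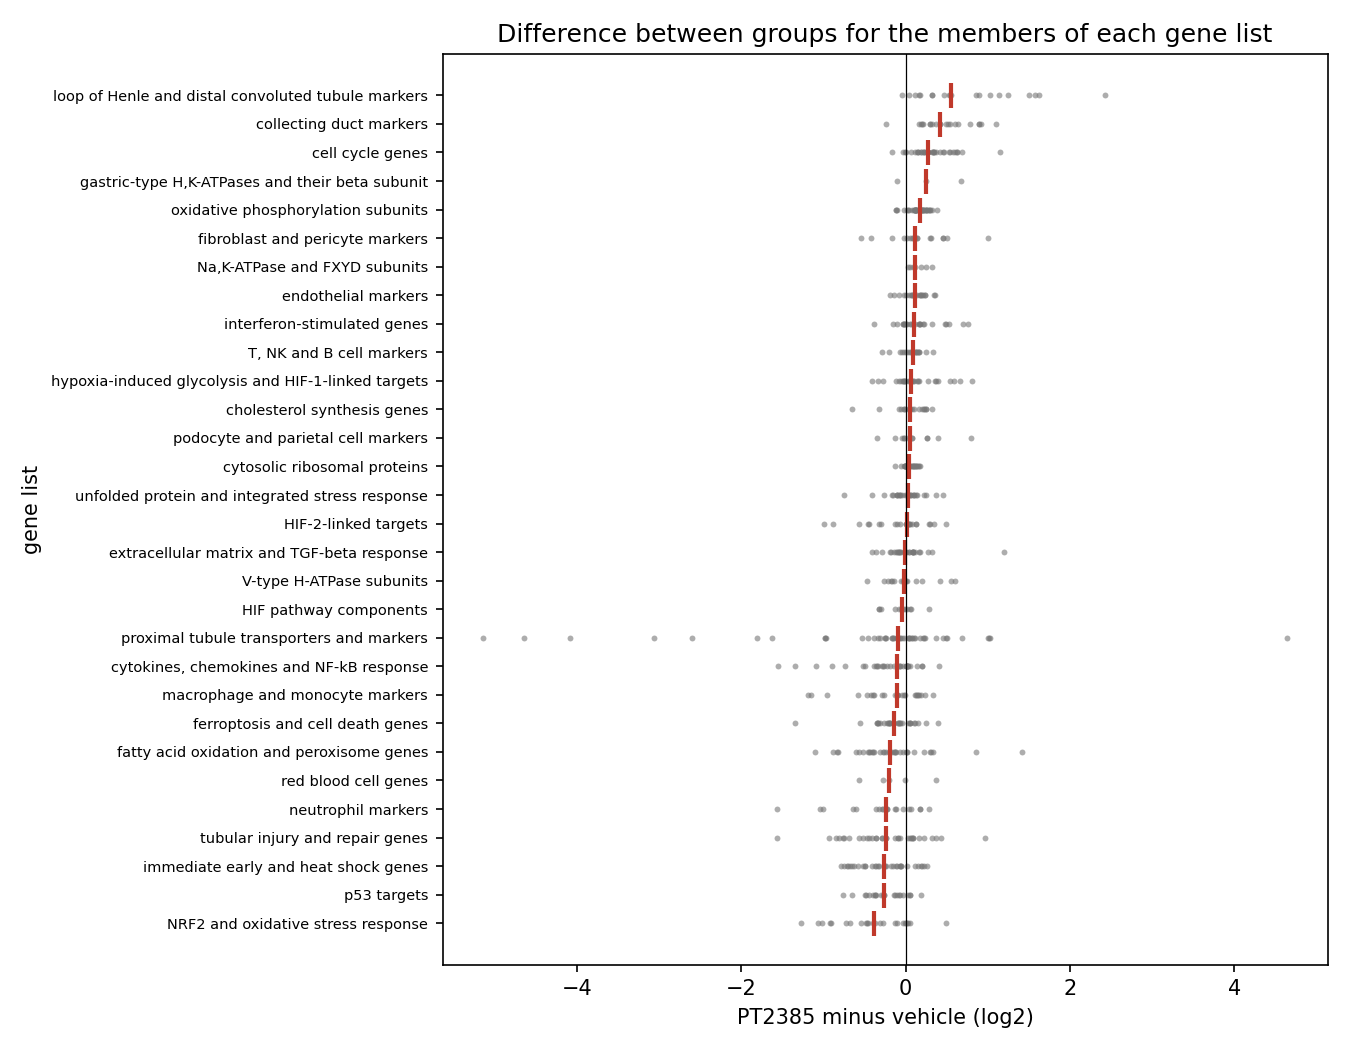
Each grey point is the difference between groups (PT2385 minus vehicle, log2, horizontal axis) of a measured member of the gene list on the vertical axis, and red marks are list medians. Medians ran from -0.38 for the NRF2 and oxidative stress response to 0.55 for loop of Henle and distal convoluted tubule markers, and the proximal tubule list held the widest range of members.

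Of 34 measured injury and repair genes 22 had lower values in the PT2385 group, and 0 of these passed the threshold over all clusters. The injury marker genes Havcr1 (-0.06, SE 0.09, adjusted p = 0.784) and Lcn2 (-0.36, SE 0.31, adjusted p = 0.635) showed no difference beyond the spread. Lcn2 had 12.28 ± 0.74 in the PT2385 group and 12.64 ± 0.19 in the vehicle group (SD, n = 3 each). Havcr1 had means of 12.34 and 12.40 in these groups. The array maxima were 13.39 to 13.49, and bright signals are compressed on an array, so differences of both genes can be understated. The injury and repair list was shifted down (34 measured, median -0.24, adjusted p = 0.0241), but adjusted p = 0.669 with an estimated correlation, and without PT2385 replicate 1 its direction turned up with adjusted p = 0.660. Its 1 member past the threshold, the ferroxidase gene Cp, was higher (0.97, SE 0.17, adjusted p = 0.0484). That call was lost without any 1 array, with median-centred arrays, with 1 cluster per gene and without the X and Y chromosomes, with adjusted p up to 0.159. Adjusted over the list alone, 2 members were higher and 4 lower. The NRF2 and oxidative stress response was shifted down (24 measured, median -0.38, adjusted p = 1.23e-07, and adjusted p = 0.308 with an estimated correlation), with 1 higher and 10 lower adjusted over the list alone. Only Ugdh, a UDP-glucose dehydrogenase gene, passed over all clusters (-0.92, SE 0.16, adjusted p = 0.0426), and its call was lost without any 1 array and with the replicate number as a block, with adjusted p up to 0.206.

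The p53 target list (23 measured, median -0.26, adjusted p = 0.000111) and the immediate early and heat shock list (34 measured, median -0.26, adjusted p = 0.000216) were shifted down. With an estimated correlation they had adjusted p = 0.308 and adjusted p = 0.589. The second lost its call without PT2385 replicate 1 (adjusted p = 0.131). The ferroptosis and cell death list was also shifted down (31 measured, median -0.14, adjusted p = 0.0138, and adjusted p = 0.308 with an estimated correlation), and lost its call without PT2385 replicate 1 (adjusted p = 0.0681). In these 3 lists 0 members passed over all clusters, and adjusted over the list alone 4 p53 targets were lower and 0 members of the other lists passed. The smallest p values were at Perp (-0.49) and Trp53inp1 (-0.77) for p53, Dusp5 (-0.68) and Klf6 (-0.70) for immediate early genes, and Bid (-0.55) and Ptgs2 (-1.34) for cell death. Cell cycle genes were shifted up (36 measured, median 0.27, adjusted p = 1.2e-06, and adjusted p = 0.541 with an estimated correlation), with 0 past the threshold over all clusters and 2 adjusted over the list alone. Ube2c had 1.15 and Aurka had 0.45. The unfolded protein and integrated stress response list showed no shift (29 measured, adjusted p = 0.994), with Phgdh at 0.37 and Sdf2l1 at 0.45, and its median (0.03) and mean (-0.01) differed in sign.

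Transcripts of the cytokines Il1b and Tnf were lower in the PT2385 group. The interleukin gene Il1b fell from 6.22 ± 0.26 to 4.67 ± 0.06 (SD, n = 3 each), a difference of -1.55 (SE 0.14, adjusted p = 0.00179), and Tnf differed by -0.74 (SE 0.10, adjusted p = 0.0151). Both group means of Il1b and the vehicle mean of Tnf (5.21) lay within the range of the background control rows. The PT2385 mean of Tnf (4.47) was no higher than the highest array median of the negative control rows (4.47), so the difference of Tnf is a lower bound in size. Which cells in the isolates carried these transcripts was not tested. The cytokine, chemokine and NF-kB list was shifted down (35 measured, median -0.10, adjusted p = 0.000642, and adjusted p = 0.541 with an estimated correlation), with 2 lower members past the threshold and 6 adjusted over the list alone. The mean difference of its members from their average over the 6 arrays was -0.321, -0.104 and 0.0544 in PT2385 replicates 1, 2 and 3 and 0.0811, 0.0515 and 0.238 in the vehicle arrays, so the groups overlapped. The granulocyte receptor gene Csf3r (-1.04, SE 0.16, adjusted p = 0.0326) was the 1 neutrophil marker past the threshold, with 3 lower adjusted over the list alone, and that list was shifted down (20 measured, median -0.23, adjusted p = 0.000726, and adjusted p = 0.308 with an estimated correlation). The lysozyme gene Lyz2 (-1.19, SE 0.16, adjusted p = 0.0202) was the 1 macrophage and monocyte marker past it, with 3 lower adjusted over the list alone. That list was shifted down (26 measured, median -0.10, adjusted p = 0.00784, and adjusted p = 0.589 with an estimated correlation) and lost its call without vehicle replicate 1 (adjusted p = 0.312). Calls of Tnf, Csf3r and Lyz2 were lost without vehicle replicate 3 or PT2385 replicate 2, among others, with adjusted p up to 0.150. Interferon-stimulated genes were shifted up (26 measured, median 0.10, adjusted p = 0.0494, and adjusted p = 0.623 with an estimated correlation), with 2 higher and 1 lower adjusted over the list alone. Ifit3 was higher (0.70, SE 0.10, adjusted p = 0.0238). The interferon list lost its call without vehicle replicate 2, vehicle replicate 3 or PT2385 replicate 1, with adjusted p up to 0.520, and Ifit3 without vehicle replicates 2 and 3 and PT2385 replicates 2 and 3, with adjusted p up to 0.136.

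Such mean differences per array overlapped between the groups for 8 of the 17 lists past the threshold, namely the injury, proximal tubule, fatty acid oxidation, fibroblast, cytokine, interferon, immediate early and cell cycle lists. In the NRF2, p53, ferroptosis and neutrophil lists they did not overlap, but PT2385 replicate 3 (0.0180, 0.00421, 0.0251 and 0.0219) lay nearest to the vehicle arrays. The lowest vehicle values of these lists were 0.0882, 0.0401, 0.0324 and 0.0872.

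Fibroblast and pericyte markers were shifted up (17 measured, median 0.12, adjusted p = 0.0494, and adjusted p = 0.541 with an estimated correlation), with Dpt at 1.00 and Lum at 0.45. Both group means of Lum (3.74 and 4.19) lay under the highest array median of the negative control rows, so no difference in expression is read from it. The fibroblast list lost the call without vehicle replicate 3 or PT2385 replicate 1 or 2, with adjusted p up to 0.660. Endothelial markers did not pass as a set (adjusted p = 0.0725, Ptprb 0.24, Plvap 0.34), and adjusted p = 0.663 with an estimated correlation, but they passed as shifted up in 7 of 17 alternatives of the data or fit, with adjusted p from 0.000753 without vehicle replicate 2 and 0.0330 without PT2385 replicate 3 to 0.0463 with the replicate number as a block. Other sets that did not pass were podocyte and parietal cell markers (adjusted p = 0.379, Mme 0.80, Ptpro -0.35) and T, NK and B cell markers (adjusted p = 0.420, Cd3d 0.33, Pax5 -0.28). Both group means of Cd3d (3.671 and 4.005) lay under the highest array median of the negative control rows, so no difference in expression is read from it. Red blood cell genes (adjusted p = 0.142, Epb42 -0.57, Klf1 -0.28) and cholesterol synthesis genes (adjusted p = 0.383, Hsd17b7 -0.66, Mvk 0.32) did not pass either, with 1 lower member each adjusted over the list alone. The PT2385 mean of Epb42 (4.23) was under the highest array median of the negative control rows, so its difference is a lower bound in size. Cytosolic ribosomal proteins gave adjusted p = 0.323 (Rps15 0.15, Rpl38 0.17), but passed as shifted up with cyclic loess (adjusted p = 0.0125) and without PT2385 replicate 1 (adjusted p = 0.000436), and adjusted p = 0.872 with an estimated correlation. The extracellular matrix and TGF-beta list gave adjusted p = 0.995 for the set, while its member Fn1, the fibronectin gene, rose by 1.20 (SE 0.17, adjusted p = 0.0208). The call of Fn1 was lost without vehicle replicate 2, vehicle replicate 3 or PT2385 replicate 2, with adjusted p up to 0.109.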

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

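Leaving out the X and Y chromosomes was chosen only after the data were seen, and gave 150 calls, all among the 184. Of 31 named genes past the threshold, 15 stayed past it under every alternative run, and 25 under every alternative other than leaving out an array. Atp4a stayed short of it throughout, with differences from 0.44 without PT2385 replicate 1 to 0.91 without PT2385 replicate 3. The count of calls moved to 456 with array weights (191 higher, 265 lower). Leaving out single arrays gave 42 to 179 calls, 14 to 76 higher and 28 to 117 lower, with smaller groups to test, and the 2-fold screen gave 145 to 233 clusters. The other alternatives gave 135 to 207 calls. The replicate number as a block gave 178 calls, 138 of them shared with the fit without it. Same-numbered arrays had correlations of their deviations of 0.138, 0.0252 and -0.0587, and 1 of 3 numbers correlated best with itself, so the numbers were not taken as pairing. The block changed the calls of 2 lists, Na,K-ATPase (adjusted p = 0.0602, lost) and endothelial markers (adjusted p = 0.0463, gained).

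Of 17 gene lists past the threshold, 9 stayed past it under every alternative of the data or fit. With an estimated correlation 0 passed: adjusted p was 0.308 for Na,K-ATPase, loop and distal, collecting duct, neutrophil, NRF2, ferroptosis and p53 lists, 0.541 for fatty acid oxidation, oxidative phosphorylation, fibroblast, cytokine and cell cycle lists, 0.589 for macrophage and immediate early lists, 0.623 for interferon, 0.663 for proximal tubule and 0.669 for injury. With fry, which asks whether a list's genes move one way on balance, only the Na,K-ATPase list passed (adjusted p = 0.00408). Its mixed test, which counts changes in either direction, passed 16 lists, among them proximal tubule (0.000159) and, with no shift past the threshold, cholesterol synthesis (0.00181), glycolysis (0.00633), V-type H-ATPase (0.036) and red blood cell genes (0.0423). It did not pass ferroptosis (0.111), injury and cell cycle (0.119), immediate early (0.222) or fibroblast (0.278). The mixed test holds no comparison with other genes, so a pass does not set a list apart from genes at large. In the test of 1 direction the other 16 of the 17 had 0.058 for collecting duct, 0.118 for loop and distal, 0.122 for NRF2, 0.139 for oxidative phosphorylation and neutrophil, 0.165 for p53, 0.174 for ferroptosis, 0.248 for cytokines, 0.271 for cell cycle, 0.305 for proximal tubule, 0.339 for fatty acid oxidation and fibroblast, 0.391 for interferon, 0.424 for macrophage and immediate early and 0.727 for injury.

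With quantile normalization adjusted p was 0.0724 for injury and interferon and 0.00837 for glycolysis and HIF-1-linked targets. With cyclic loess it was 0.0956, 0.0911 and 0.00461 for these, and 0.0125 for ribosomal proteins. Median-centring gave 0.0713 for injury. Without the dimmest 20% of clusters fibroblast markers had 0.104, and without the dimmest 40% they had 0.0538, injury 0.215, macrophage 0.0673, ferroptosis 0.0705 and glycolysis 0.0278. An eBayes trend gave 0.0477 for glycolysis. Array weights gave 0.0515 for Na,K-ATPase, 0.0386 for glycolysis, 0.146 for injury and 0.279 for interferon. Over the omissions of single arrays adjusted p ran from 0.0398 to 0.103 for Na,K-ATPase, 0.0315 to 0.163 for glycolysis, 1.15e-05 to 0.660 for injury, 3.09e-10 to 0.373 for proximal tubule, 0.00696 to 0.660 for fibroblast, 0.000226 to 0.312 for macrophage, 0.00124 to 0.520 for interferon, 0.00211 to 0.0681 for ferroptosis and 9.73e-09 to 0.131 for immediate early genes. Endothelial markers, which also passed with the block, had 0.0240 with quantile normalization, 0.0277 with cyclic loess, 0.0426 without the dimmest 40%, 0.0347 with array weights and 0.000753 to 0.649 over the omissions of single arrays, and ribosomal proteins had 0.000436 to 0.849 over these. The injury list turned upward without PT2385 replicate 1 (0.660). The cause of these shifts was not tested. Signals within the range of the background control rows, up to 7.47, limit what dim genes can show.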

Other observations

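The tests of cell shares, injury and drug alone, and the enrichment by gene family, were chosen only after the results were seen. Genes were grouped into families by the letters that open their symbols, and near-identical copies, whose symbols differ only in a last letter, were counted as 1 gene. Among 212 families of at least 10 genes, 2 held more calls than their size gives (Fisher's exact test, 1-sided, Benjamini-Hochberg adjusted). Cytochrome P450 genes had 7 calls among 94 (0.765 by chance, adjusted p = 0.00123), from Cyp2j13 (-4.88) to Cyp4a14 (1.42), with Cyp2e1 at -2.60 and Cyp4b1 at -1.62. UDP-glycosyltransferase genes, those with symbols that open with Ugt, had 4 calls among 11 (adjusted p = 0.000281), with Ugt2b37 (-2.38), Ugt8a (-1.98) and Ugt2b38 (-1.81) lower and Ugt2b34 (1.18) higher. Chemokine and Serpina genes passed only with copies counted separately (adjusted p = 0.00255 and adjusted p = 0.0318), and with copies merged they had adjusted p = 0.378 and adjusted p = 1. Their calls were Ccl28 (2.00), Ccl21a (0.64) and Ccl21b and Ccl21c, which had equal values (0.81 each), and Serpina1f (2.79), Serpina1a (1.44) and Serpina1c (1.12), all higher in the PT2385 group. Other related genes in a family can still share signal, so calls within a family are not independent.

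The Y-linked genes Eif2s3y, Uty and Kdm5d had means between 6.47 and 9.20 in the vehicle group. In the PT2385 group they had 2.99 to 3.32, under the median of the background control rows (3.60). The labels give no sex, but these values argue against the same sex in both groups and go with male vehicle and female PT2385 mice. Tests listed after these genes were seen, but before the tested values were read, went with that: 5 of 5 measured genes that escape X inactivation were higher in the PT2385 group, with a median difference of 0.281, none past the threshold (Kdm6a 0.45, adjusted p = 0.0723). Of 12 measured kidney genes of known sex bias 11 had the direction of male vehicle and female PT2385 mice, with only Slc22a12 (-0.98) past the threshold. Several of the largest autosomal calls, such as Slco1a1, Slc7a13, Cyp4a12a, Akr1c18 and Slc7a12, are also known for sex bias in mouse kidney. Treatment group and Y-linked expression came apart in 0 of 6 arrays, so an effect of PT2385 alone on the autosomal calls and a difference in sex cannot be told apart.

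Among markers of the loop of Henle and distal tubule 19 of 20 had higher values in the PT2385 group, 2 past the threshold, as had 20 of 21 of the collecting duct, none past it, and the set calls were lost with an estimated correlation (adjusted p = 0.308 for each list). An equal rise in the share of all these cells as the whole cause would move markers found only in them by a similar amount. Of 41 markers 16 had a 95% interval that left out the median of their list, from Dmrt2 (-0.24) to Egf (2.43), where chance gives 5%. Some of these genes are also expressed elsewhere and the brightest are compressed on an array, which spreads the markers under an equal rise too. The test therefore cannot decide, and an equal rise and separate changes by segment both stay open. A milder injury may also contribute: the injury list had a median of -0.235 with quartiles of -0.506 and 0.0729, which leaves this undecided. For these markers too, an effect of sex and an effect of PT2385 cannot be told apart, for the reason given above.

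Proximal tubule genes moved in both directions. Fewer proximal tubule cells in the PT2385 isolates would lower the whole list. It had a median of -0.0894 and a lower quartile of -0.36, while the 8 members called lower had a median of -2.20 and 2 were called higher. The called members were picked by a threshold that favours large differences. The gap between them and the whole list was therefore largely fixed beforehand and decides nothing. The proximal tubule genes Lrp2 and Slc34a1, named in advance, differed by 0.03 (SE 0.21) and -0.15 (SE 0.30). Their values argue against a loss of these cells as the whole cause of called falls as large as -2.20. A smaller loss cannot be excluded. A difference in sex and an effect of PT2385 stay open here, for the reason given above.

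The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 184 clusters, 1 of the 10 splits gave as many, and the highest of the others was 0.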
